A study of Nitrospirillum amazonense with 6 samples.

How the data were processed

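Total RNA was depleted of ribosomal RNA, starting from 7 µg, and sequenced on an Ion Proton instrument, per the labels' protocols. The file is 1 table for all 6 libraries. Reads per gene were deposited by the authors as whole-number counts and, beside them, as RPKM, both under a heading of CLC Genomics Workbench 7.5.1, per the file headers. The submitters' processing notes also name DESeq2 and edgeR, and the table repeats reads under a heading for each. The aligner settings, the genome build and whether counting used strand were not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as the 4 GroEL genes, are therefore uncertain as to which gene they belong to.

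The deposited table was checked before use. RPKM followed from reads, gene length and column total in 6148 rows, within 0.5% or 0.01. The authors' mean RPKM columns had nearly equal sums (1132962 in control and 1132961 with apoplast fluid) and the same maximum (46848.44) in both groups. The maxima of plain means differed (16781 and 76916). The authors' columns had therefore been normalised across libraries and were not used for tests. Of the p-value cells under the DESeq2 heading 602 were above 1, and 786 under the EdgeR heading, so neither column was used. Under the CLC heading 17 p-value cells were above 1, and that column was only compared with the calls made here. The rows of 35 genes, with 0.54% of reads, were left out because the read columns disagreed with each other or the row was out of order, and 1 row that names no gene was left out. The table held 0 ribosomal RNA rows. Gene Y958_RS00005 has coordinates that span its replicon, so its length was not used.

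The counts under the CLC heading were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust estimation, TMM scaling and filterByExpr with a minimum count of 10. This left 4207 of 6114 genes. CPM values use the TMM library sizes, the SE of a log2 fold change is its size over the square root of F, and the common coefficient of biological variation was 24.5%. Groups were taken from the sample titles, and the fit had no block. Gene lists were matched to product names, and of 40 such lists the 36 with 5 or more tested genes were tested by camera of limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. The list of structural RNA matched only methyltransferases and was not used. The table gives no gene symbols, so symbols refer to the most abundant gene with that product name.

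Genes named in the report follow a rule: the 10 highest and 10 lowest log2 fold changes among called genes with separate groups, a mean CPM of 10 or more and a known product, up to 2 called members per direction of each list, and a fixed set of nitrogen, motility, stress and carbon genes. Tests, lists, this rule and most alternatives were fixed before the data were examined. Single values per library were compared by exact permutation tests. The 3 flasks of a group came from separate cell suspensions, which the labels call biological triplicates. Pairs of libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 4.33 to 19.2), so no pair was taken as copies of 1 library.

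The functions were tested on simulated data drawn from the real means and depths for this comparison, with 4163 genes tested by edgeR. It recovered 100% of 4-fold and 8-fold changes, 40.4% of 2-fold and 6.25% of 1.5-fold changes, and called 7 of 3968 unchanged genes. The simulation gave all genes the same dispersion and changed few of them, equally up and down. In the real data 56.0% of genes were called, so these rates may not carry over. Alternatives covered scaling, filters, thresholds, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, the reads under the DESeq2 heading, and lists without mismatched names. Columns of p-values above 1 kept the deposited DESeq2 and edgeR results from being compared with each other.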

Results

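Messenger RNA of the nitrogen-fixing bacterium Nitrospirillum amazonense strain CBAmC was compared after 2 h with and without sugarcane apoplast fluid, the liquid of the spaces between plant cells. Cells were grown for 16 h at 30 °C with 5 g per L sucrose and 10 mM sodium glutamate. At an optical density of 1.4, each of 3 cell suspensions was split between a flask that received LGI growth medium (control) and a flask that received apoplast fluid. Each group had 3 libraries, called replicates A, B and C. The deposited table held 6149 genes on 4 replicons. Reads counted in genes were 203595, 1084304 and 669841 in control replicates A, B and C, and 358771, 487242 and 1262623 in the apoplast fluid replicates. One read corresponded to 4.20 CPM (counts scaled to library size) in control replicate A and to 0.748 CPM in apoplast fluid replicate C, so genes of low abundance were measured least precisely in the former. Total reads did not separate the groups (exact two-sided permutation test, p = 1, n = 3 per group). The 10 most abundant genes of each library took 10.4% ± 1.02 of control reads and 17.4% ± 3.37 of reads with apoplast fluid (SD, n = 3, exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 allows).

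The comparison of the groups asks how apoplast fluid changes gene expression in this bacterium. Phage shock protein A, an RND efflux pump and the chaperone DnaK were among the genes that rose with apoplast fluid, and a TonB-dependent receptor, cbb3 oxidase subunits, fructokinase and an ammonia channel were among those that fell. Of the gene lists, limma's camera called ribosomal proteins, translation factors, nucleotide biosynthesis, the tricarboxylic acid cycle and oxidative stress higher. It called chemotaxis, flagellum, cyclic di-GMP, TonB receptors and amino acid uptake lower. These calls used a preset correlation, and none held with an estimated correlation (smallest adjusted p = 0.445). Of 4207 genes tested, 2356 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1163 higher and 1193 lower. At least 2-fold changes were called for 959 genes that were higher and 1021 that were lower, and at least 4-fold changes for 338 and 445. In 61.6% of the genes tested the 3 libraries of one group lay above the 3 of the other, where chance gives 10%. The first principal component of log2 CPM held 80.6% of the variance and separated the groups. Libraries of one group correlated across genes at r = 0.92 to 0.98 and libraries of different groups at r = 0.56 to 0.65. Genes are not independent replicates, so these values describe the libraries only.

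Among called genes with a known product, propionyl-CoA--succinate CoA transferase (Y958_RS19590, bases 1439171 to 1440688 of the second replicon) rose from 7.36 ± 6.47 to 1167 ± 501 CPM (SD, n = 3), a log2 fold change of 6.94 ± 0.51 (SE, edgeR adjusted p = 6.24e-08). In the same region, the TonB-dependent siderophore receptors Y958_RS19645 and Y958_RS19685, outer membrane proteins that take up iron-binding molecules, rose by 6.45 ± 0.60 and 5.12 ± 0.49 on the log2 scale. The efflux adaptor Y958_RS27945 and the RND efflux pump Y958_RS27950 rose by 5.42 ± 0.49 (4.67 without apoplast fluid replicate B) and 5.32 ± 0.38, while the efflux adaptor Y958_RS17665 changed by -4.65 ± 0.30. Of 49 multidrug efflux genes, 18 rose and 12 fell (19 and 13 adjusted over the list alone), and camera did not call the list (adjusted p = 0.239). Phage shock protein A, which protects the inner membrane under envelope stress, rose by 5.15 ± 0.38 (Y958_RS10570) and, for a second gene of that name, by 4.26 ± 0.34 (Y958_RS01375). An ABC transporter substrate-binding protein (Y958_RS25425) rose by 6.10 ± 0.53, from 5 control reads, all in control replicate B. Without that library the fitted change was 9.68, a value that depends on the prior count because no control read is left, and without control replicate C it was 5.48. Another efflux adaptor (Y958_RS19575), an acetyltransferase (Y958_RS05655) and a transcriptional regulator (Y958_RS04000) rose by 5.08 ± 0.54, 4.93 ± 0.61 and 4.74 ± 0.32. Y958_RS05655 had 4 control reads, and its change was 5.66 without control replicate B and 4.32 without control replicate C.

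Among called genes with a known product, a TonB-dependent receptor (Y958_RS21555) fell from 7911 ± 1876 to 26.6 ± 14.4 CPM, a log2 fold change of -8.33 ± 0.46 (edgeR adjusted p = 2.58e-08). ABC transporter genes changed by -6.86 ± 0.48 (Y958_RS25245), -5.82 ± 0.43 (Y958_RS17655) and -5.69 ± 0.38 (Y958_RS17660). The last 2 are annotated next to the efflux adaptor Y958_RS17665, and what they transport is not given. A carbohydrate porin (Y958_RS14955) changed by -5.74 ± 0.44, with 6 reads left in the 3 treated libraries, and by -6.63 without apoplast fluid replicate C. Subunit I (Y958_RS06210) and subunit II (Y958_RS06215) of cbb3 cytochrome c oxidase, a terminal oxidase with high affinity for oxygen, changed by -4.78 ± 0.36 and -5.39 ± 0.37, and its assembly chaperone (Y958_RS06220) by -5.69 ± 0.61. The last rests on 7 treated reads and was -7.23 without apoplast fluid replicate A and -4.76 without apoplast fluid replicate C. Alcohol dehydrogenase Y958_RS30540, helicase Y958_RS04940 and AAA family ATPase Y958_RS26750 changed by -5.58 ± 0.38, -5.55 ± 0.32 and -5.54 ± 0.35.

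**Figure D1:**
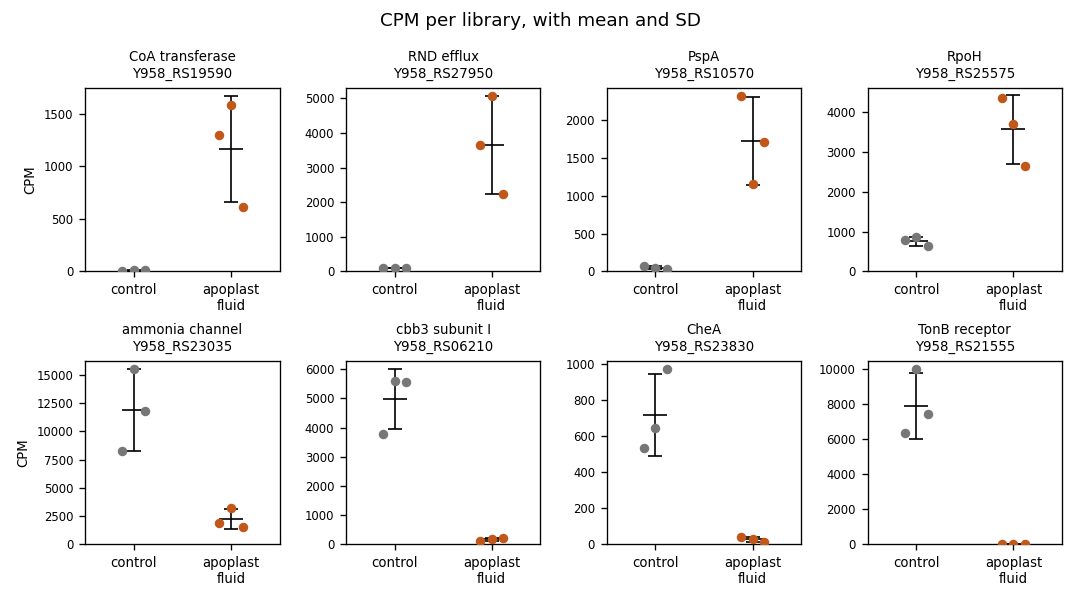
CPM of 8 genes (vertical axes, linear, starting at 0) in control and apoplast fluid libraries, with points for the 3 libraries of each group and bars for the mean and SD. The 3 libraries of one group lay apart from the 3 of the other for each gene, for example 7911 against 26.6 CPM for the TonB receptor. The rule that picked the CoA transferase, the RND efflux pump, PspA and the TonB receptor required separate groups. Their separation is therefore no finding, and the other genes shown were picked among called genes.

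Most chemotaxis genes fell with apoplast fluid. Of 55 chemotaxis genes tested, 39 fell and 3 rose (39 and 4 adjusted over the list alone), with a median log2 fold change of -1.48. The signalling kinase CheA (Y958_RS23830) changed by -4.80 ± 0.40 and a methyl-accepting chemotaxis protein (Y958_RS25095) by -3.82 ± 0.32, while the chemotaxis protein Y958_RS04465 rose by 2.63 ± 0.35. The chemotaxis list was called by limma's camera (adjusted p = 3.86e-07 with a preset correlation, adjusted p = 0.445 with an estimated correlation). Of 33 flagellar genes, 14 fell and 2 rose, in both adjustments, among them motor proteins MotB (Y958_RS09055, -2.10 ± 0.33) and MotA (Y958_RS09625, 2.91 ± 0.33). Flagellin Y958_RS19300 fell from 649.7 ± 185 to 163 ± 12.8 CPM. The most abundant flagellin (Y958_RS13655) had 8089 ± 1631 and 7802 ± 2315 CPM and was not called. The flagellar list had a median of -0.73 and an adjusted p = 0.0305 in camera, and adjusted p = 0.647 with an estimated correlation. Its call was lost without control replicate B (adjusted p = 0.0631), without control replicate C (0.0589), without apoplast fluid replicate A (0.0703), without apoplast fluid replicate C (0.054) and with a filter at a mean CPM of 10 (0.0521). Of 17 genes of cyclic di-GMP and quorum sensing, 11 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.08, an adjusted p = 0.00372 and, with an estimated correlation, adjusted p = 0.445. The GGDEF domain protein Y958_RS06260 changed by -2.44 ± 0.27.

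Most genes of ribosomal proteins, translation and nucleotide biosynthesis rose. Of 53 ribosomal protein genes, 39 rose and 0 fell (40 and 0 adjusted over the list alone), with a median of 1.01, and their mean share of reads was 5.85% in control and 9.16% with apoplast fluid. L27 (Y958_RS11360) and L21 (Y958_RS11365) rose by 2.70 ± 0.26 and 2.55 ± 0.28. Of 41 translation factor and tRNA ligase genes, 24 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.80. Glutamate--tRNA ligase (Y958_RS08030) rose by 2.66 ± 0.28 and a tyrosine--tRNA ligase (Y958_RS25755) changed by -2.45 ± 0.37. Of 27 purine and pyrimidine biosynthesis genes, 18 rose and 3 fell (19 and 3 adjusted over the list alone), with a median of 0.89. IMP dehydrogenase (Y958_RS07685) was among those that fell (-2.25 ± 0.28). The camera adjusted p of the 3 lists was 6.31e-09, 2.60e-04 and 0.00644, and with an estimated correlation each had adjusted p = 0.445.

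Central metabolism changed in both directions. Of 27 genes matched to the tricarboxylic acid cycle, 14 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.0438, and adjusted p = 0.482 with an estimated correlation). Its call was lost without control replicate A (adjusted p = 0.0616) and without control replicate C (0.0673). Isocitrate dehydrogenase genes Y958_RS06140 and Y958_RS06150 rose by 2.10 ± 0.28 and 1.98 ± 0.29, and citrate synthase (gltA, Y958_RS08035) by 1.22 ± 0.31. One of the members that fell, 3-isopropylmalate dehydrogenase (Y958_RS30545, -3.58 ± 0.30), is an enzyme of leucine synthesis rather than of the cycle. Single genes of fructose use that fell were fructokinase (Y958_RS28825) at -5.18 ± 0.39, the fructose phosphotransferase subunit (Y958_RS14960) at -5.14 ± 0.41 (-6.73 without apoplast fluid replicate C) and 1-phosphofructokinase (Y958_RS14965) at -3.94 ± 0.35. Glucose-6-phosphate dehydrogenase (zwf, Y958_RS18505) and phosphogluconate dehydratase (edd, Y958_RS18500) were not called, at -0.01 ± 0.28 and 0.29 ± 0.25, and the former changed sign with DESeq2 size factors. The glycolysis list and the sugar uptake list were not called by camera (adjusted p = 0.639 and 0.309). In the former 5 genes rose and 4 fell, with a median of 0.27 and a mean of -0.08. Poly-beta-hydroxybutyrate polymerase (Y958_RS30590) changed by -3.94 ± 0.33 and a polyhydroxyalkanoate depolymerase (Y958_RS01280) rose by 3.28 ± 0.35, while another (Y958_RS26765) changed by -3.46 ± 0.42. Of the 8 genes of that list 3 rose and 2 fell, in both adjustments, with a median of 0.0057 and a mean of -0.15, and camera did not call it (adjusted p = 0.94).

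Of 27 amino acid and peptide uptake genes, 16 fell and 0 rose, in both adjustments, with a median of -1.02 (camera adjusted p = 0.00372, and adjusted p = 0.445 with an estimated correlation). The gene annotated as peptide permease (Y958_RS17650) changed by -4.27 ± 0.31. It ends at base 976786 of the second replicon, and Y958_RS17655, named above beside an efflux adaptor, starts at base 976812. Its place among uptake genes therefore rests on its product name only. Of 69 genes of TonB-dependent receptors and the TonB system, 36 fell and 7 rose, in both adjustments, with a median of -0.87 (camera adjusted p = 0.00472, and adjusted p = 0.445 with an estimated correlation). Receptor Y958_RS22280 changed by -4.04 ± 0.29, while siderophore receptors Y958_RS23265 and Y958_RS04510 rose by 4.04 ± 0.37 and 3.54 ± 0.34. The siderophore list, which shares members with it, had 8 genes that rose and 5 that fell of 18 and was not called (adjusted p = 0.0703).

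**Figure D2:**
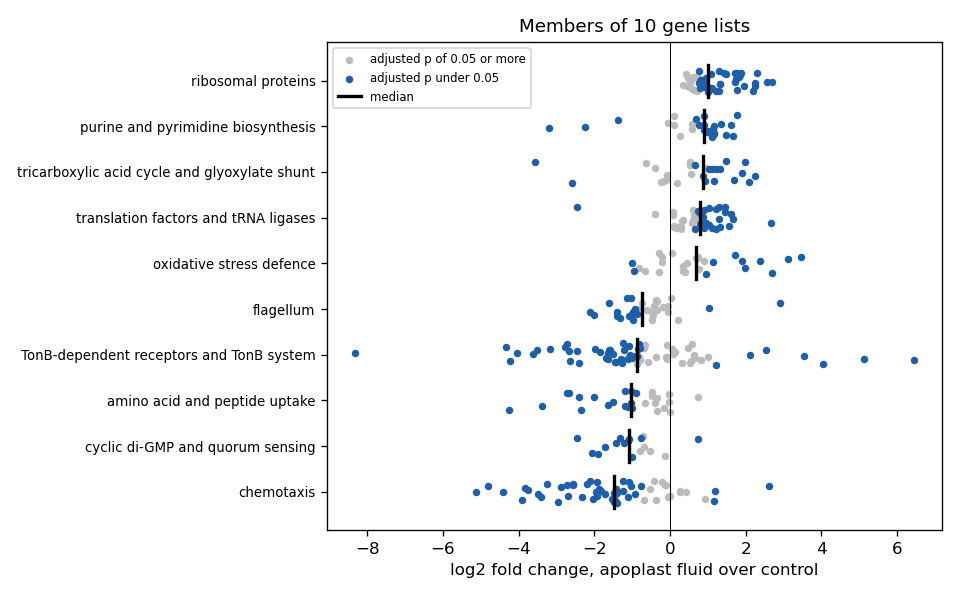
Log2 fold change of apoplast fluid over control (horizontal axis) of each tested member of the 10 lists that camera called with the preset correlation, with a point per gene and a black line at the median. Medians run from -1.48 for chemotaxis to 1.01 for ribosomal proteins.

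Nitrogen genes split. The ammonia channel (amtB, Y958_RS23035) fell from 11881 ± 3631 to 2211 ± 884 CPM, a log2 fold change of -2.43 ± 0.37, and the nitrogen regulator NR(I) (ntrC, Y958_RS07810) changed by -1.34 ± 0.24. The P-II signalling proteins Y958_RS20390 and Y958_RS00375 rose by 2.06 ± 0.28 and 2.53 ± 0.35. Glutamine synthetase (glnA, Y958_RS20395) was at 5432 ± 1288 and 4988 ± 620 CPM and was not called. The nitrogenase genes nifH, nifD and nifK had 7, 19 and 20 reads over the control libraries and 8, 24 and 21 over the treated ones, and did not pass the low-count filter, so they were not tested. Among other untested genes of nitrogenase and its assembly, NifE had 14 control and 52 treated reads, NifB 12 and 38, and NifS 1 and 15. NifN had 12 and 11, and the remaining untested genes had at most 7 reads in either group. Of 18 genes matched to nitrogenase and its assembly, 3 were tested. FixH (Y958_RS06235), which belongs with the cbb3 oxidase genes, changed by -3.36 ± 0.30, and the iron-sulfur cluster proteins Y958_RS00115 and Y958_RS03520 rose by 3.14 ± 0.34 and 2.91 ± 0.37. The list of nitrogen regulation, matched by product name, did not include the ammonia channel Y958_RS23035 or the glutamine synthetase Y958_RS20395. It had 3 genes that rose and 1 that fell of 7 and was not called (camera adjusted p = 0.562).

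DnaK (Y958_RS00570) rose from 8333 ± 1186 to 27760 ± 14404 CPM (1.74 ± 0.39), GroEL (Y958_RS12730, 1 of 4 copies by product name) by 1.49 ± 0.38 (0.91 without apoplast fluid replicate B), Hsp33 (Y958_RS12635) by 4.03 ± 0.39 and the heat shock sigma factor RpoH (Y958_RS25575) by 2.24 ± 0.30. An Hsp20 family protein (Y958_RS26755) changed by -5.24 ± 0.35. Of 36 genes of the heat shock list, 20 rose and 5 fell (21 and 5 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0647, and adjusted p = 0.696 with an estimated correlation). Settings that called it included those without apoplast fluid replicate C (adjusted p = 0.00932), with a filter at a mean CPM of 10 (0.0484) and without mismatched names (0.0115). Of 27 oxidative stress genes, 9 rose and 2 fell, in both adjustments, with a median of 0.68 (camera adjusted p = 0.0445, and adjusted p = 0.445 with an estimated correlation). That call was lost without control replicate A (adjusted p = 0.0655), without control replicate C (0.0653), without apoplast fluid replicate A (0.0768) and with a filter at a mean CPM of 10 (0.0527). Alkyl hydroperoxide reductase subunit F (Y958_RS19915) rose by 3.12 ± 0.35, and catalase-peroxidase (katG, Y958_RS13295) was not called, at -0.21 ± 0.41. Superoxide dismutase (sodB, Y958_RS17500) rose by 0.94 ± 0.34, a call lost without control replicate B (edgeR adjusted p = 0.101), without control replicate C (0.15) and without apoplast fluid replicate A (0.137).

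Fold changes in the authors' deposited table, from CLC Genomics Workbench, correlated with those computed here at r = 0.99 (Pearson) and 0.987 (Spearman) across 4207 genes, and 4003 had the same sign. Of these genes, 2121 had a p-value under 0.05 in the authors' deposited table, and 1928 of those were called here. A further 428 genes were called here only and 193 in that table only. The calls here used adjusted p-values, and the deposited column does not say whether its p-values were adjusted, so the thresholds may differ. With unadjusted edgeR p under 0.05, 2576 genes passed here. Both tests used the same reads.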

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

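The reads under the DESeq2 heading, the rows of uncertain identity and the lists without mismatched names were chosen as alternatives after seeing the data. The count of 2356 genes moved between 1814 (adjusted p under 0.01) and 2519 (no low-count filter) over these settings, and no called gene changed sign. Without scaling beyond library totals the median of all genes moved by -0.23 on the log2 scale, and 39.8% of 2206 calls were higher, against 49.4%. Leaving out each library gave 1929 to 2449 genes. DESeq2 called 2077 and did not call 372 of the 2356. With the replicate block 2358 genes were called, and 70 of the 2356 were not. Deviations from the group means of same-letter libraries correlated at 0.15 (A), 0.26 (B) and -0.17 (C), and not every library correlated best with its own letter. Each suspension was split between the groups, but the labels do not say that a letter marks a suspension, so the letters were not taken as pairs. Depth limits genes of few reads, such as nitrogenase.

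The number of lists called was less firm: 10 with the preset correlation, 0 with an estimated one, whose smallest adjusted p was 0.445, and 22 with fry, which asks a different question. It was 7 to 10 without each library in turn, 9 with a filter at a mean CPM of 10, 12 with the replicate block and 13 without mismatched names. The block added heat shock and siderophores (adjusted p = 0.0399 each), and the removal of mismatched names added heat shock (0.0115), organic acid transport (0.0385) and mobile elements (0.0161). Among lists not called, medians close to 0 changed sign, and the cause was not tested. Removing mismatched names gave -0.23 for nitrogen regulation and 0.66 for osmoprotection. Glycoside hydrolases had 0.011 with DESeq2 size factors and 0.025 with upper-quartile scaling, and exopolysaccharide had 0.010 with the latter. With the replicate block, type III, IV and VI secretion had -0.054 and polyhydroxyalkanoates -0.053. Without each library in turn, medians ran from -0.13 to 0.16 for the respiratory chain, -0.093 to 0.30 for aromatic compounds, -0.22 to 0.067 for glycoside hydrolases, -0.44 to 0.36 for secretion, -0.42 to 0.063 for exopolysaccharide, -0.18 to 0.16 for polyhydroxyalkanoates, -0.13 to 0.010 for sigma factors, -0.29 to 0.10 for nitrogen oxides, -0.26 to 0.28 for metals and -0.17 to 0.099 for osmoprotection. Of the genes not called, glnA (Y958_RS20395) ran from -0.28 to 0.066, flagellin (Y958_RS13655) from -0.29 to 0.069 and zwf (Y958_RS18505) from -0.34 to 0.15, the last at 0.028 with DESeq2 size factors and 0.026 in DESeq2. The planned change to ribosomal RNA rows moved nothing, since the table held 0, and those for tables without counts did not apply.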

Other observations

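The tests of copy number as the whole cause and of low-oxygen genes were chosen after the result was seen, and the bounds for the tests of chance and of correlation within lists were set after it. The most abundant gene with apoplast fluid was a hypothetical protein (Y958_RS13520), at 510 ± 98.3 CPM in control and 56333 ± 20300 CPM in treated libraries (log2 fold change 6.78 ± 0.45, n = 3). PspC (Y958_RS01385), encoded close to PspA, rose by 4.25 ± 0.34, and a serine protease (Y958_RS20070) by 4.57 ± 0.42. Several genes between Y958_RS30525 and Y958_RS30590 fell, among them universal stress proteins Y958_RS30525 (-4.13) and Y958_RS30535 (-4.85), alcohol dehydrogenase Y958_RS30540 (-5.58) and the polymerase Y958_RS30590 (-3.94). Crp/Fnr family regulator Y958_RS01065 changed by -2.23 ± 0.28, and Y958_RS01790 fell from 859 ± 282 to 49.8 ± 20.2 CPM. These genes were picked after their values were seen.

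A list of genes tied to low oxygen by product name (cbb3 and cytochrome d oxidases, universal stress proteins, oxygen-independent coproporphyrinogen oxidase, nitrous-oxide reductase, pseudoazurin) was written after cbb3 genes had been seen to fall. Of its 18 tested genes, 17 fell and 0 rose, with a median of -3.39. Of the 11 outside the cbb3 region, 6 are universal stress proteins, which also answer to other conditions. A candidate explanation is that treated cells were less short of oxygen than control cells. The list was chosen for the pattern and oxygen is not among the labels, so the median is no test of this hypothesis, which stays open.

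Of 550 pairs of called genes less than 50 bases apart, 96.2% had the same direction, against 46.0% to 61.0% in 1000 shuffles within replicons and 69.2% of 237 pairs at least 500 bases apart.

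Median log2 fold changes were 0.29, -0.05, -0.47 and -0.61 on the 4 replicons, 0.90 apart at most, which a change in replicon copy number could give. On the third replicon, the shifts from the first of the 10th and 90th percentiles were -1.24 and -0.35. These shifts differed by 0.89 (95% interval 0.11 to 1.62, resampling runs of 20 neighbouring genes). On replicons 2 and 4 that interval included 0. Copy number alone forecasts equal shifts only for replicons of like gene content, so these intervals cannot say whether it is the whole cause. Copy number stays open, as does the different gene content, with 49 of 53 ribosomal protein genes on the first replicon. Of the 69 genes of the TonB list, 21 are on the third replicon and 13 on the fourth. Camera compared each list with all other tested genes, so differences between replicons were not taken out of the list calls.

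The real grouping gave 2356 genes and the highest of the other splits of the 6 libraries 0, and for lists 10 against 9. With 10 splits, of which 1 gave as many, the share cannot fall under 0.05. Each other split also mixed control and treated libraries on both sides. The group difference then adds to the spread within a side, and part of it remains between the sides. Neither the 0 genes nor the 9 lists therefore measure what chance gives. Length-matched random lists argue against gene length as the whole cause of the list calls. Of the 10 called lists, 9 had medians outside their central 95%, oxidative stress being the exception. Cyclic di-GMP was barely outside (-1.084 against a bound of -1.058). The random genes were drawn singly, while close neighbours changed together, so these ranges may be too narrow. Correlation between genes of a list above the preset value remains a candidate explanation. In camera 0 of the 10 kept an adjusted p under 0.05 with an estimated correlation, but a lost call need not come from correlation. In simulated data with genes drawn independently, a raised list of 49 genes had a camera adjusted p of 9.65e-17 with the preset correlation. With an estimated correlation it had 0.018. The lost calls therefore cannot say whether correlation is the cause. The single genes named do not rest on these list calls.

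An IS110 family transposase (Y958_RS01355) had 0 reads under the CLC heading and 264 control and 160 treated reads under the DESeq2 heading. A hypothetical protein (Y958_RS14515) had 0 against 32 and 10. Both (100%) share their product name and a length within 10% with another gene. The name hypothetical protein is given to 1919 genes, so the match of Y958_RS14515 says nothing about copies. Also, 2 genes are too few to say whether copies share reads.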
